A study of Mus musculus with 8 samples.

How the data were processed

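Messenger RNA was sequenced from 8 samples of cultured mouse adipocytes. Per the labels' protocols, cells of the stromal vascular fraction, the cells that sediment when fat tissue is digested with collagenase and that include the precursors of adipocytes, were grown almost to confluence and transfected with locked nucleic acid (LNA) inhibitors, short modified oligonucleotides that bind a microRNA and block it, at 100 nM. They were returned to full medium after 8 h, induced to differentiate with insulin, dexamethasone, 3-isobutyl-methylxanthine and rosiglitazone, and harvested at day 4. The labels do not name the fat depot; the series title speaks of brown adipocytes. Libraries were made from 5 µg of total RNA with a directional kit. The 4 groups of 2 samples each were an inhibitor of miR-182, an inhibitor of miR-203, an inhibitor of miR-708 and a control transfection, and groups were taken from the sample titles. The labels do not say whether the 2 samples of a group came from separate animals or cultures, so the authors' p-values may measure technical spread only, and they do not say what the control cultures were transfected with.

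The submitters' processing notes name TopHat2 version 2.0.9 for alignment, Cuffdiff version 2.1.1 and the mouse build mm10, and the options, the gene annotation and the use of strand in counting are not given in the sources used here. The authors deposited 3 tables, each with 18933 genes, and each comparing one inhibitor with the control. FPKM (fragments per kilobase of transcript, scaled for library size by a method that the sources do not state) stand in the deposited tables as 1 value per group. The column headers name only the group, and the values are taken here as pooled by the authors over its 2 samples. Each deposited table also gives the authors' log2 fold change, p-value and q-value for every gene. The control FPKM were identical in the 3 tables. The authors' log2 fold change equalled the log2 ratio of the 2 FPKM within 0.01 for 18931, 18929 and 18929 genes. Genes with p and q of exactly 1 (4542, 4562 and 4617) were taken as not tested, which left 14391, 14371 and 14316 tested genes for miR-182, miR-203 and miR-708. The smallest p-value in each deposited table was 5e-05, with a q-value of 0.00176, so that strongly changed genes share this value and are not ranked by it. Benjamini-Hochberg adjustment over the tested genes of the 3 tables together gave 0.00101 as its smallest value, so the authors' q-values were adjusted over a different set of tests than these tables hold. Dates had replaced 23 gene symbols in each table, and these were restored through the gene identifier. A further 2 lines held no values.

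Pooled values carry no spread between replicates. No SD, interval or test across samples could therefore be computed, and a call of "higher" or "lower" is always the authors' own, at q below 0.05, in the deposited tables. The sequencing depth of each sample is unknown, since FPKM from Cuffdiff hold no read counts, so no counting interval is given. FPKM are relative values whose scaling between samples is not stated. In the authors' tables, 6809 genes lie in 2762 loci given to 2 or more genes, up to 98 genes in one. Reads of overlapping genes and of near-identical copies may therefore have been divided between them.

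From the FPKM, log2((inhibitor + 1) / (control + 1)) was computed for each gene, a scale that understates the change of genes with low values. Folds printed beside FPKM are plain ratios of the 2 pooled values. Before the data were examined, 20 gene lists were fixed, 14 for pathways and tissue functions and 6 for markers of other cell types that such a culture could hold. For each list, the members with a test and with an FPKM of at least 1 in either group are called measured. Their median log2 ratio was set against the medians of 10000 random lists of the same size matched on mean expression in 10 bins, and its percentile is a description of these libraries, not a test across replicates. Lists with fewer than 5 measured members got no percentile. List members were also counted by the authors' calls over all genes, and again after the authors' p-values were adjusted over the list alone by the Benjamini-Hochberg method. The genes named were chosen by a rule set before the data were examined: 11 genes of brown fat and its precursors in every comparison, the 6 called genes with the largest rise and the 6 with the largest fall in this log2 ratio at an FPKM of at least 5 in either group, the 2 called members with the largest change of each list with at least 2 called members (4 where 8 or more were called), and the 4 genes with the largest change in each direction among genes called alike in all 3 comparisons. Other members are named where a count is small or where a list has no called member, and these were chosen after their values were seen.

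Overlaps of calls were set beside the product of the list sizes divided by the genes tested in both, and beside 100 simulations of unchanged groups that share one control, drawn with standard errors derived from the authors' log2 fold changes and p-values on the assumption that the control contributes at most as much error as an inhibitor group. The pooled control could not be split. For the seed analysis, the longest annotated 3' UTR of each gene was taken from GENCODE M21, an annotation of the same mouse build, which matched 97.8% of the gene identifiers and gave a 3' UTR for 14634 genes. Matches to positions 2 to 8 of each microRNA (7mer-m8, or 8mer with an A after the match) were counted, and the median of genes with a site was set against 10000 random gene sets matched on 3' UTR length in 10 bins and on expression in 5 bins. Gene coordinates are those of GENCODE M21.

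The list percentiles were tested on simulated data for the miR-182 comparison with 12846 genes, of which 200 were changed. Among 400 lists of 20 changed genes, the list median lay outside the central 95% of random lists in 6.5% of lists with no shift, in 24.5% with a log2 shift of 0.1 and in 94.5% with a shift of 0.3. The simulated genes varied independently of each other. These rates therefore do not hold for lists whose members vary together between samples, as members of one pathway may. Alternatives set before the data were examined were a stricter q, a minimum change, another pseudocount, other FPKM minimums, subtraction of the median log2 ratio, the authors' fold change without pseudocount, recomputed q-values, 8mer sites and other matching. Alternatives added after the data were seen were random lists matched on transcript length or GC content, adjustment over the 3 tables together, genes of at least 300 bases and list medians with untested genes kept. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Mature microRNA levels and values per sample were not analysed here.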

Results

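Gene expression was compared between differentiating mouse adipocyte cultures in which one of 3 microRNAs was blocked and control cultures, with the question whether miR-182, miR-203 and miR-708 are needed for the differentiation of brown adipocytes. There were 8 samples, 2 for each inhibitor and 2 for the control transfection. The values are FPKM taken as pooled by the authors over the 2 samples of a group. They carry no replicate error, and the depth of each sample is unknown. A gene is said to have risen or fallen only where the authors' deposited table calls it at q below 0.05. The authors' tables called 2105 genes for the miR-182 inhibitor (1209 higher, 896 lower), 1039 for the miR-203 inhibitor (678 higher, 361 lower) and 1082 for the miR-708 inhibitor (646 higher, 436 lower). The median log2 ratio of measured genes was close to 0 in each comparison, at -0.014, -0.012 and -0.019. Scaling between samples can itself hold such a median near 0, so it is not read as a result.

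The blocked microRNAs are transcribed from Mir182 on chromosome 6 (30165918 to 30165992, minus strand), Mir203 on chromosome 12 (112130880 to 112130955, plus strand) and Mir708 on chromosome 7 (96249424 to 96249532, plus strand) of mm10. Mir708 lies inside the protein-coding gene Tenm4, on the same strand, and the other 2 genes lie in no protein-coding gene of the annotation. None of the 3 has a row in the authors' deposited tables, and mature microRNA levels were not analysed here, so how far each microRNA was blocked is not shown by these values. Tenm4 stood at 29.5 FPKM in the control and 18.97 FPKM with the miR-708 inhibitor and was not called in the authors' deposited table (q = 0.0715).

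With the miR-182 inhibitor, Ucp1 and Cidea, which mark brown fat, fell. Ucp1, the mitochondrial uncoupling protein that lets brown fat make heat (chromosome 8, 83290352 to 83298452), went from 203.03 FPKM in the control to 67.7 FPKM, 3.00-fold lower. Cidea, a lipid droplet protein abundant in brown adipocytes (chromosome 18, 67343604 to 67367785), went from 297 to 56.2 FPKM, 5.29-fold lower. Both had q = 0.00176 in the authors' deposited table. Ppargc1a, Prdm16 and Pparg were not called in that table. Ppargc1a, a coactivator of mitochondrial genes, stood at 23.9 FPKM in the control and 21.1 with the inhibitor. Prdm16, a regulator of brown fat identity, stood at 5.40 and 7.26, and Pparg, the main transcription factor of adipocyte differentiation, at 136 and 139. Of 18 measured members of the brown adipocyte and thermogenic list, the authors' deposited table called 5 lower (Ucp1, Cidea, Cox7a1, Cox8b and Kcnk3), 2 higher (Adrb3 and Otop1) and 11 neither, with 5 lower and 2 higher adjusted over the list alone. The list's median log2 ratio of -0.21 lay at percentile 1.4 of matched random lists.

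General adipocyte genes went both ways with the miR-182 inhibitor. Of the 20 measured members, 3 rose, 2 fell (Slc2a4 and Dgat2) and 15 were not called in the authors' deposited table, with 7 higher and 2 lower adjusted over the list alone. The median log2 ratio of 0.035 lay at percentile 79.7. Adipoq, the adipocyte hormone adiponectin, rose 1.62-fold (q = 0.00591 in the authors' deposited table), the transcription factor Cebpa rose 1.41-fold (q = 0.00327) and Cfd, the serine protease adipsin, rose 1.77-fold (q = 0.00176). Fabp4, a fatty acid carrier of adipocytes, stood at 37475 FPKM in the control and 34042 with the inhibitor and was not called. Among 4 measured white-fat selective genes, Agt (1.56-fold) and Nnmt (2.16-fold) were called higher in the authors' deposited table and none lower, also when adjusted over the list alone.

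Genes of mitochondrial energy metabolism stood slightly lower. In the authors' deposited table, 4 of 44 nuclear oxidative phosphorylation genes fell with the miR-182 inhibitor (Ndufa4, Uqcrq, Cox5a and Cox6a1) and none rose, with 6 lower adjusted over the list alone. The list median of -0.25 lay at percentile 0.01. Cox5a, a subunit of cytochrome c oxidase, fell 1.42-fold and Uqcrq, a subunit of complex III, 1.32-fold. For the tricarboxylic acid cycle, 3 of 17 genes fell in the authors' deposited table (Cs, Sucla2 and Pdhb), 7 adjusted over the list alone, with a median of -0.26 at percentile 0.82. For fatty acid oxidation, 1 of 19 was called lower (Acot2, 2.14-fold) and 1 higher (Ehhadh, 1.31-fold) in that table, 4 and 2 adjusted over the list alone. The median was -0.24, at percentile 0.815. Fatty acid and triglyceride synthesis stayed inside the range of random lists (median -0.067, percentile 33.9). The authors' deposited table called 4 of its 20 genes lower, 5 adjusted over the list alone: Pck1, the gluconeogenic and glyceroneogenic carboxykinase (1.75-fold), Lpin1 (1.35-fold), Scd2 and Fads1. Of 21 measured cholesterol genes, the authors' deposited table called 4 higher and 2 lower, 5 and 2 adjusted over the list alone, with a median of 0.29 at percentile 99.98. Mvk, mevalonate kinase, rose 1.96-fold, Insig1, a sterol-responsive regulator of SREBP processing, rose 1.43-fold, and Idi1 fell 1.85-fold.

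Precursor, matrix and cell cycle genes rose with the miR-182 inhibitor. Of 11 measured preadipocyte and progenitor genes, 9 rose and 1 fell in the authors' deposited table, the same numbers as adjusted over the list alone, with a median log2 ratio of 0.74 at percentile 100. Pdgfra and Pdgfrb, receptors found on adipocyte precursors, rose 1.90-fold (10.9 to 20.8 FPKM) and 1.72-fold (6.67 to 11.5 FPKM). Ly6a, the surface antigen Sca1, rose 3.83-fold, Pi16 3.72-fold (0.562 to 2.09 FPKM) and Wisp2 2.61-fold. Members below 1 FPKM in the control, such as Pi16, counted only because their inhibitor value reached 1 FPKM, which favours rises. For Pi16 this held in all 3 comparisons. Klf2 fell 2.21-fold. Among 26 extracellular matrix genes, 22 rose and none fell in that deposited table, 24 adjusted over the list alone, with a median of 0.81 at percentile 100. Col3a1, a fibrillar collagen, went from 389 to 841 FPKM, and the gelatinase Mmp2 from 43.6 to 119.8 FPKM. Timp1, an inhibitor of such proteases, rose 2.88-fold and Thbs2 2.36-fold. In the cell cycle list, 19 of 24 genes rose and none fell in the authors' deposited table, 22 adjusted over the list alone, with a median of 0.74 at percentile 100. Mcm5, a subunit of the replicative helicase, went from 1.68 to 4.84 FPKM and Plk1, a mitotic kinase, from 2.79 to 6.79 FPKM. Mcm6 rose 2.42-fold and Birc5 2.26-fold.

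Interferon-stimulated genes had the highest median of the 20 lists with the miR-182 inhibitor. Of 17 measured members of the interferon list, 15 rose and none fell in the authors' deposited table, 16 adjusted over the list alone, and the median log2 ratio of 1.51 lay at percentile 100. Members below 1 FPKM in the control, such as Oasl2 and Rtp4, counted only because their inhibitor value reached 1 FPKM, which favours rises. With the miR-203 and miR-708 inhibitors 13 members were measured, so the 3 interferon medians are not over the same genes. Isg15, a ubiquitin-like modifier induced by interferon, went from 1.13 to 14.9 FPKM, Bst2, the antiviral protein tetherin, from 8.53 to 64.2 FPKM, Oasl2 from 0.247 to 7.53 FPKM and Rtp4 from 0.261 to 8.13 FPKM. These 4 were also among the 6 largest rises, as ranked by log2 of FPKM plus 1 at an FPKM of at least 5, together with Ifi27l2a (25.9 to 241 FPKM) and H2-Q6 (0.777 to 10.6 FPKM). H2-Q6 is a class I histocompatibility gene whose value is uncertain because it shares sequence with near-identical copies. Of 10 measured inflammatory and acute phase genes, 4 rose and 1 fell in the authors' deposited table, 7 and 1 adjusted over the list alone, with a median of 0.65 at percentile 100. Saa3, an acute phase protein, rose 3.09-fold and Lcn2, lipocalin, fell 3.02-fold. The endoplasmic reticulum and amino acid stress list moved the other way. In the authors' deposited table, 6 of 15 genes fell and 1 rose (Pdia4), the same numbers as adjusted over the list alone, with a median of -0.33 at percentile 0.09. Trib3, a stress-induced pseudokinase, fell 3.07-fold and Ddit3, the stress transcription factor CHOP, 2.16-fold. By the same ranking, the largest falls were in Porcn (6.06-fold), Mreg (6.53-fold), Cidea, Coro6 (5.41-fold), Cystm1 (5.18-fold) and Kalrn (6.72-fold).

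Markers of other cell types were mostly below 1 FPKM. Measured members numbered 2 for macrophages, 1 each for endothelial, mesothelial and red blood cells, 3 for skeletal muscle and 6 for smooth muscle and pericytes in the miR-182 comparison. The authors' deposited table called the macrophage marker Lyz2 lower (3.32 to 1.46 FPKM), with 2 lower adjusted over the list alone. It called the mesothelial marker Krt19 higher (5.56 to 8.77 FPKM), 1 adjusted over the list alone, and the skeletal muscle marker Des lower (5.89 to 2.76 FPKM), with 1 lower and 1 higher adjusted over the list alone. Among smooth muscle and pericyte markers Mylk rose 2.44-fold and Cspg4 fell 1.68-fold in that table (2 higher and 1 lower adjusted over the list alone), with a median of 0.20 at percentile 89.1. The measured endothelial marker (Egfl7, 22.6 to 29.2 FPKM) and red blood cell marker (Alas2, 0.741 to 1.34 FPKM) were not called, nor was either when adjusted over the list alone. Below 1 FPKM and so outside these counts, the authors' deposited table called the endothelial marker Cdh5 (0.334 to 0.627 FPKM, q = 0.00591) and the smooth muscle marker Myh11 (0.267 to 0.455 FPKM, q = 0.00463) higher. The same held for Mx2 of the interferon list (0.0603 to 0.575 FPKM).

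**Figure D1:**
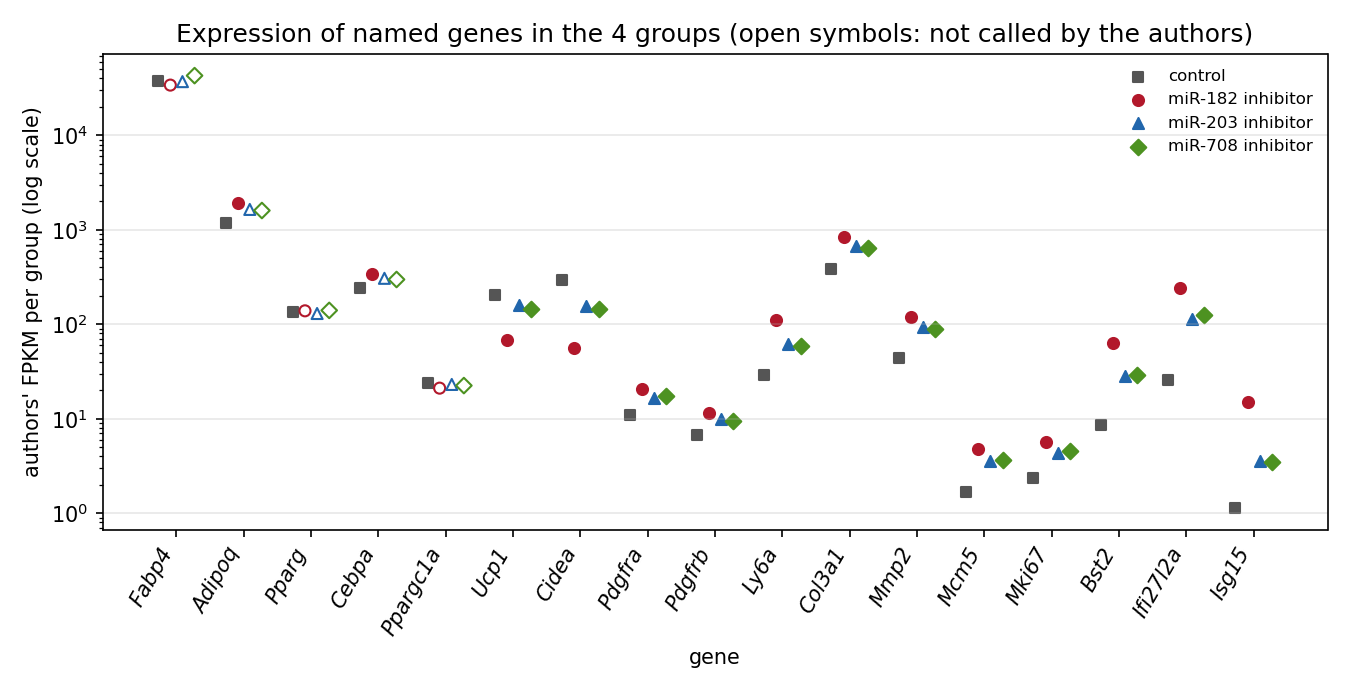
Pooled FPKM (log scale) of 17 genes in the control and the 3 inhibitor groups, 1 point per group, with open symbols for inhibitor values that the authors did not call at q below 0.05. Cidea stood at 297 FPKM in the control and at 56.2, 157 and 146 FPKM with the inhibitors of miR-182, miR-203 and miR-708, while Bst2 stood at 8.53 FPKM in the control and at 64.2, 28.1 and 28.8 FPKM.

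With the miR-203 inhibitor, Cidea fell 1.90-fold to 157 FPKM (q = 0.00176 in the authors' deposited table) and Ucp1 fell 1.28-fold to 159 FPKM, with a q of 0.0493 that is close to the threshold. Ppargc1a (23.1 FPKM), Prdm16 (6.11 FPKM), Pparg (130 FPKM), Fabp4 (37047 FPKM), Cebpa (307 FPKM), Adipoq (1644 FPKM) and Insig1 (270 FPKM) were not called in that table. Of the 18 brown adipocyte genes, 2 fell, 1 rose (Otop1, 1.34-fold) and 15 were not called, with 3 lower and 1 higher adjusted over the list alone. The median of -0.073 lay at percentile 14.1. In the general adipocyte list 1 of 20 rose (Cfd) and none fell, the same as adjusted over the list alone, with a median of 0.044 at percentile 80.6. Agt (1.31-fold) and Nnmt (1.45-fold) rose among 4 white-fat selective genes, 3 adjusted over the list alone.

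Precursor and matrix genes rose here too. In the authors' deposited table for miR-203, 9 of 11 progenitor genes rose and 1 fell (9 and 1 adjusted over the list alone; median 0.51, percentile 100). Among them were Pdgfra (1.52-fold), Pdgfrb (1.49-fold), Ly6a (2.11-fold), Pi16 (2.64-fold), Wisp2 (2.11-fold) and Dlk1, an inhibitor of adipocyte differentiation (1.66-fold). Of 26 matrix genes 17 rose and none fell (23 adjusted over the list alone; median 0.55, percentile 100). Mmp2 stood at 2.16-fold, Thbs2 at 1.80-fold, Col3a1 at 1.72-fold and Mmp14 at 1.67-fold. The cell cycle list held 15 of 24 genes called higher and none lower (19 adjusted over the list alone; median 0.48, percentile 100). Mcm5 stood at 2.14-fold, Ccnb2 at 1.86-fold, Mki67 at 1.85-fold and Birc5 at 1.75-fold. Of 13 measured interferon genes 10 rose and none fell (11 adjusted over the list alone; median 0.90, percentile 100). Among them were Oasl2 (7.63-fold), Rtp4 (7.41-fold), Bst2 (3.30-fold) and Isg15 (3.16-fold). Inflammatory genes counted 3 higher and 1 lower of 7 (3 and 1 adjusted over the list alone; median 0.29, percentile 99.2), with Saa3 2.25-fold higher and Lcn2 2.33-fold lower.

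Metabolic lists moved little with the miR-203 inhibitor. No gene of the oxidative phosphorylation list (44 genes, median -0.087, percentile 0.68) or the tricarboxylic acid cycle list (17 genes, median -0.13, percentile 0.94) was called in the authors' deposited table, nor adjusted over the list alone. Both medians lay below the central 95% of random lists. Acot2 was the 1 fatty acid oxidation gene of 19 that fell (1 adjusted over the list alone; median -0.092, percentile 5.125). No gene of 20 was called for fatty acid and triglyceride synthesis on either count (median -0.043, percentile 23.4). Idi1 was the 1 called cholesterol gene of 21, lower in the authors' deposited table (1 lower and 1 higher adjusted over the list alone; median 0.12, percentile 99.3). In the stress list Trib3 (1.64-fold) and Ddit3 (1.39-fold) fell and 13 of 15 genes were not called (4 lower and 1 higher adjusted over the list alone; median -0.11, percentile 4.185). The largest rises, ranked as above, were Ifi27l2a (4.44-fold), the zinc finger gene Zbtb38 (4.14-fold), Rpph1, the RNA of ribonuclease P (3.47-fold), RP23-81C12.3, annotated as a long intergenic noncoding RNA (3.10-fold), H2-Q7 (3.80-fold, with the same doubt about copies as H2-Q6) and Apod (3.34-fold). Rpph1 is among the structural RNA loci taken up in the last paragraph, where a difference between libraries is not excluded. Nor is such a difference excluded for RP23-81C12.3. Sh2d6 (3.88-fold), Coro6 (3.01-fold), Kalrn (3.12-fold), Mreg (2.69-fold), Porcn (2.58-fold) and Smox (2.81-fold) fell the most by this ranking. Among marker lists, Mylk rose 1.72-fold and Cspg4 fell 1.33-fold of 6 smooth muscle and pericyte markers (2 higher and 1 lower adjusted over the list alone; median 0.26, percentile 97.4). Myl1 rose 1.99-fold and Des fell 2.09-fold of 3 skeletal muscle markers (1 and 1 adjusted over the list alone). The 2 macrophage, 1 endothelial and 1 mesothelial markers measured were not called on either count, and no red blood cell marker was measured. Below 1 FPKM, the authors' deposited table called Icam1 of the inflammatory list higher (0.408 to 0.920 FPKM).

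With the miR-708 inhibitor, Cidea fell 2.03-fold to 146 FPKM (q = 0.00176) and Ucp1 fell 1.39-fold to 146 FPKM (q = 0.00327) in the authors' deposited table. Ppargc1a (22.5 FPKM), Prdm16 (4.91 FPKM), Pparg (140 FPKM), Fabp4 (42888 FPKM), Cebpa (298 FPKM), Adipoq (1601 FPKM) and Insig1 (273 FPKM) were not called. Of 18 brown adipocyte genes these 2 fell and 1 rose (Otop1), 2 and 1 adjusted over the list alone. The median of -0.17 lay at percentile 0.93. The general adipocyte list held 1 gene called higher (Cfd, 1.63-fold) and 1 lower (Plin4, 1.30-fold) of 20, 2 and 2 adjusted over the list alone, with a median of 0.10 at percentile 94.6. Nnmt rose among 4 white-fat selective genes, 3 adjusted over the list alone.

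The same precursor, matrix and interferon lists stood high for miR-708. In the authors' deposited table, 9 of 11 progenitor genes rose and 1 fell (9 and 1 adjusted over the list alone; median 0.62, percentile 100). Pdgfra stood at 1.59-fold, Pdgfrb at 1.41-fold, Pi16 at 2.58-fold, Ly6a at 2.04-fold, Wisp2 at 1.76-fold and Dlk1 at 1.58-fold. Of 26 matrix genes 15 rose and none fell (23 adjusted over the list alone; median 0.51, percentile 100). Mmp2 stood at 2.03-fold, Col3a1 and Postn at 1.66-fold and Mmp14 at 1.64-fold. The cell cycle list had 17 of 24 genes called higher and none lower (20 adjusted over the list alone; median 0.54, percentile 100). Mcm5 stood at 2.21-fold, Mcm6 at 2.01-fold, Mki67 at 1.97-fold and Birc5 at 1.76-fold. Of 13 measured interferon genes 8 rose and none fell (11 adjusted over the list alone; median 1.00, percentile 100). Oasl2 stood at 10.3-fold, Rtp4 at 8.33-fold, Bst2 at 3.38-fold and Iigp1 at 2.64-fold. Inflammatory genes counted 3 higher and 1 lower of 8 (3 and 1 adjusted over the list alone; median 0.40, percentile 99.97), with Saa3 2.49-fold higher and Lcn2 2.60-fold lower. In the stress list 3 of 15 genes fell and 1 rose (4 and 1 adjusted over the list alone; median -0.17, percentile 1.07), with Atf3 1.94-fold and Trib3 1.70-fold lower.

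No oxidative phosphorylation gene of 44 (median -0.096, percentile 0.69) and no tricarboxylic acid cycle gene of 17 (median -0.14, percentile 1.88) was called for miR-708 in the authors' deposited table, nor adjusted over the list alone. Pdk4 (1.84-fold) and Acot2 (1.56-fold) fell among 19 fatty acid oxidation genes (2 adjusted over the list alone; median -0.11, percentile 3.87). No gene of 20 was called for fatty acid and triglyceride synthesis on either count (median -0.092, percentile 6.77). Of 21 cholesterol genes Mvk rose 1.64-fold and Idi1 fell 1.45-fold (1 and 1 adjusted over the list alone; median 0.13, percentile 99.2). The largest rises, ranked as above, were Ifi27l2a (4.80-fold), Cfb, a complement factor (4.29-fold), Apod (3.87-fold), H2-Q7 (4.25-fold), Arhgap27 (5.30-fold) and Bst2. The largest falls were Coro6 (3.75-fold), Kalrn (4.25-fold), Porcn (3.36-fold), Car6 (4.36-fold), Sh2d6 (3.37-fold) and Mreg (2.90-fold). Mylk rose 1.87-fold and Cspg4 fell 1.60-fold of 6 smooth muscle and pericyte markers (1 and 1 adjusted over the list alone; median 0.20, percentile 96.0). Myl1 rose 1.94-fold and Des fell 1.84-fold of 4 skeletal muscle markers (1 and 1 adjusted over the list alone). The 2 macrophage, 1 endothelial, 1 mesothelial and 1 red blood cell markers measured were not called. Adjusted over the list alone, 1 macrophage marker was lower and the mesothelial marker higher. Below 1 FPKM, the authors' deposited table called the endothelial marker Pecam1 (0.318 to 0.839 FPKM, q = 0.00928) and Icam1 (0.408 to 0.808 FPKM) higher.

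**Figure D2:**
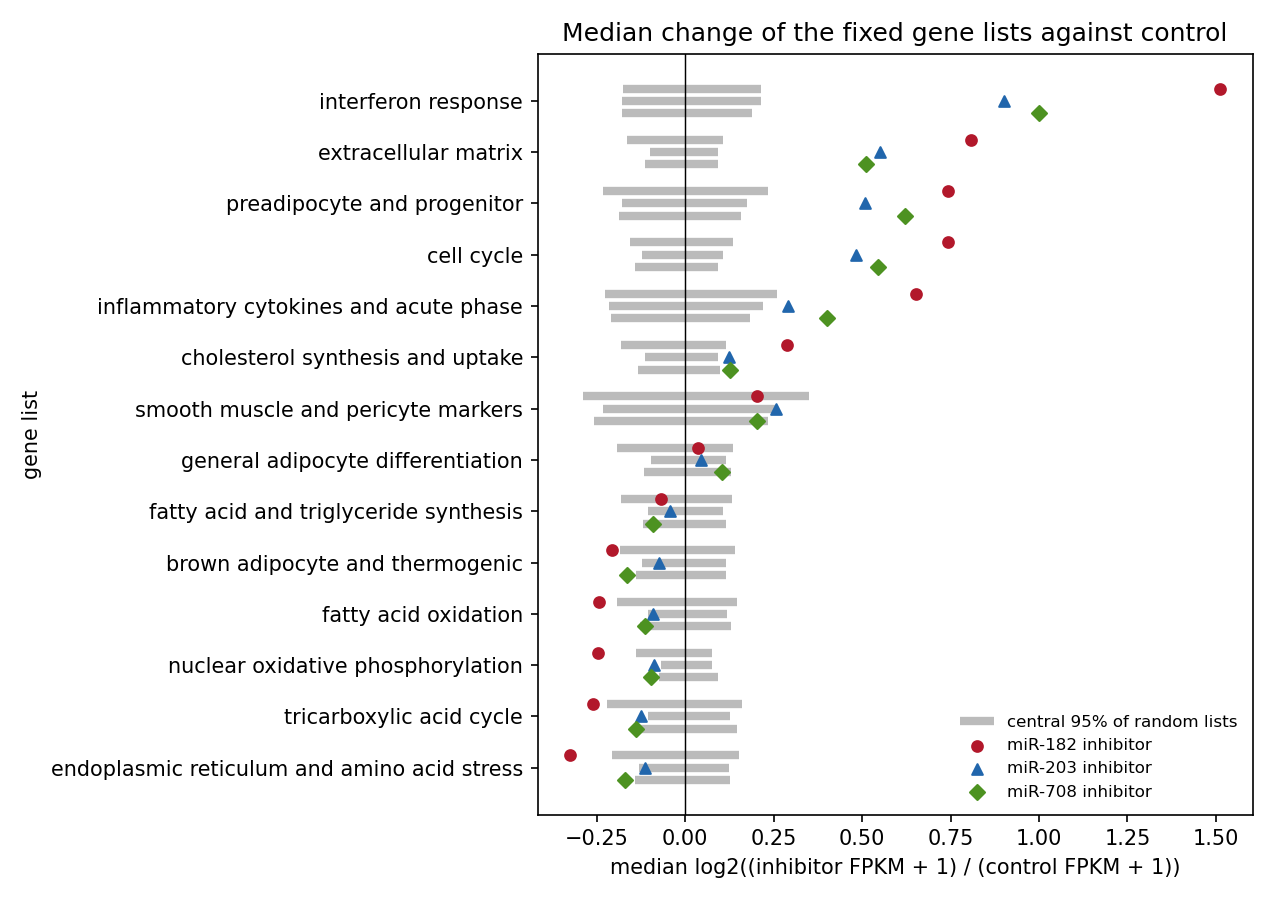
Median log2((inhibitor FPKM + 1) / (control FPKM + 1)) (horizontal axis) of each list with at least 5 measured members, 1 point per inhibitor, with grey bars for the central 95% of 10000 random lists matched on expression. The interferon medians of 1.51, 0.90 and 1.00 and the matrix medians of 0.81, 0.55 and 0.51 lie right of their bars for the miR-182, miR-203 and miR-708 inhibitors.

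Many genes differed from the control alike in the 3 comparisons, which all use the same control samples. The authors' deposited tables called 453 genes higher and 229 lower in all 3 comparisons, and no gene was called higher in one and lower in another. By the smallest of the 3 changes in log2 of FPKM plus 1, the 4 genes with the largest shared rises were Ifi27l2a, H2-Q7, Apod and Bst2. The 4 with the largest shared falls were Abcb1a, a drug efflux pump, Sh2d6, Coro6 and Kalrn. Abcb1a stood at 3.64 FPKM in the control and at 0.14, 0.153 and 0.144 FPKM with the inhibitors of miR-182, miR-203 and miR-708. Its values were alike with the inhibitors, so a difference of the control samples alone is not excluded for it. In 608 of the 682 genes called in all 3 tables (89.1%), the miR-182 inhibitor gave the largest log2 ratio in size. Whether single genes differed between inhibitors was not tested. Genes called higher in both of a pair numbered 592 for miR-182 and miR-203, 593 for miR-182 and miR-708 and 461 for miR-203 and miR-708, where independent lists of these sizes would share 56.3, 54.0 and 30.3. Genes called lower in both numbered 282, 374 and 240, against 22.8, 27.6 and 11.1. Simulated unchanged groups with a shared control shared 0.85, 0.97 and 0.7 higher genes and 0.88, 0.93 and 0.94 lower genes on average. These simulations drew errors from the authors' p-values, which may measure technical spread only, and limited the error of the control. They therefore cannot show how many genes a control that differed from all other cultures would make the comparisons share.

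Across 12531 genes, which are not independent replicates, the log2 ratios correlated with r = 0.72 for miR-182 and miR-203, 0.77 for miR-182 and miR-708 and 0.73 for miR-203 and miR-708, against 0.28, 0.28 and 0.30 for the simulated unchanged groups. The covariances were 0.153, 0.165 and 0.121, against simulated values of 0.0567, 0.0580 and 0.0575, which leaves differences of 0.0965, 0.107 and 0.0632. The pooled control could not be split, so part of the excess may come from the shared control samples. Contrasts with no sample in common gave r = 0.33 for miR-182 over miR-203 with miR-708 over control and r = 0.28 for miR-182 over miR-708 with miR-203 over control. It was -0.065 for miR-203 over miR-708 with miR-182 over control, each across 13156 genes.

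The seed analysis asked whether predicted targets of a blocked microRNA stood higher than other genes. Genes with a 7mer-m8 or 8mer site of the blocked microRNA had medians inside the central 95% of gene sets matched on 3' UTR length and expression in each comparison. Of these genes, 8.79%, 4.58% and 3.81% were called higher for miR-182, miR-203 and miR-708. Among genes without a 6mer match, which were not matched on 3' UTR length, the shares were 9.66%, 5.67% and 5.85%. With sets matched on expression alone, the medians lay below that range for miR-182 (percentile 0.77) and miR-708 (percentile 0.01). Among genes with a 7mer-m8 or 8mer site in the 3' UTR, the median log2 ratio minus that of genes without a 6mer match was -0.025 for miR-182 (1513 genes with a site, percentile 9.76 of matched sets), -0.010 for miR-203 (1945 genes, percentile 78.8) and -0.037 for miR-708 (1914 genes, percentile 6.09). Against the median of the matched sets, the differences were -0.0096, 0.0030 and -0.0074. With 8mer sites alone, the miR-182 genes (625) stood lower, with a difference of -0.047, at percentile 0.665. Genes with a site of another blocked microRNA stayed between percentiles 9.915 and 94.3 in the 6 crossed cases with 7mer-m8 or 8mer sites. With 8mer sites alone, the miR-182 genes also stood low in the miR-203 comparison (percentile 6.12) and the miR-708 comparison (percentile 2.84), both inside the central 95% of matched sets, and the difference between comparisons was not tested. The genes with 8mer sites of the blocked microRNA lay at percentile 60.2 for miR-203 and 95.9 for miR-708, 0.0019 and 0.027 above the median of the matched sets.

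**Figure D3:**
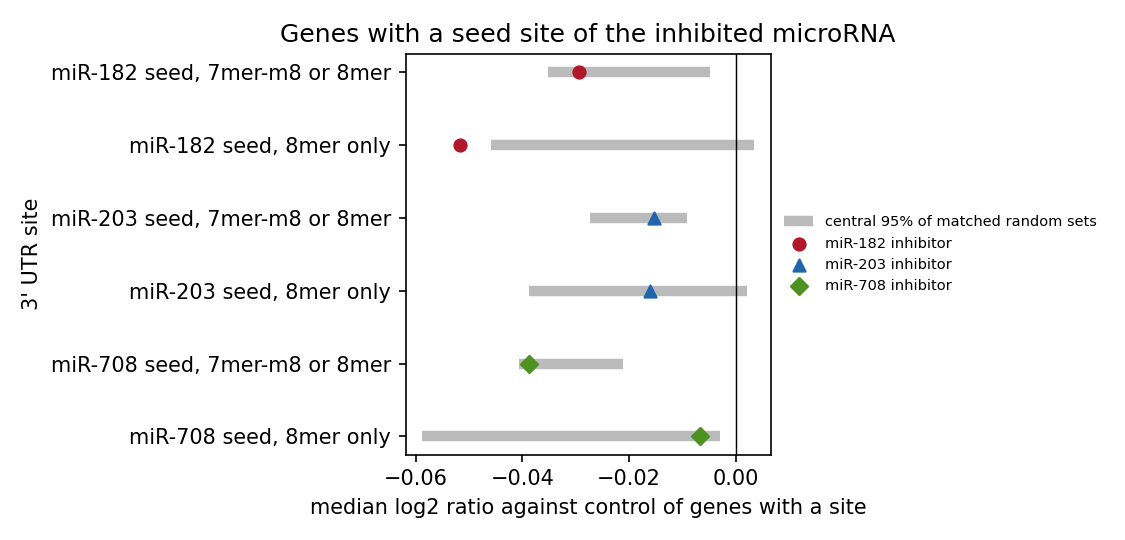
Median log2 ratio against control (horizontal axis) of genes with a 3' UTR site of the microRNA blocked in that comparison, with grey bars for the central 95% of 10000 gene sets matched on 3' UTR length and expression. The points for 7mer-m8 or 8mer sites lie inside their bars, and the miR-182 point for 8mer sites alone lies left of its bar.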

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

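Tests chosen after the data were seen were the length-matched and GC-matched random lists, adjustment over the 3 tables together, genes of at least 300 bases and list medians with untested genes kept. No paired analysis was possible because the deposited tables hold 1 pooled value per group, and for the same reason the alternatives that leave out each replicate or use the replicate number as a block were not run. No call, list median outside the central 95% of random lists or named gene reversed its direction under an alternative run. The seed shift for miR-708 changed side of its matched sets, inside their central 95%, from percentile 6.09 to 95.9 with 8mer sites alone, and that for miR-203 did so, also inside it, with matching on expression alone; the cause was not tested. Named genes kept their direction and side of the threshold in 629 of their alternatives and lost the call in 15, all at q below 0.01, Ucp1 with the miR-203 inhibitor among them (log2 fold change -0.36, q = 0.0493); the stricter threshold itself is the cause. List medians stayed on the same side of the central 95% of random lists in 329 alternatives and moved outside it in 4: smooth muscle and pericyte markers with the miR-203 inhibitor with no FPKM minimum (0.26, percentile 98.4) and with length matching (0.26, percentile 97.9), the same list with the miR-708 inhibitor at a pseudocount of 0.1 (0.29, percentile 97.6), and general adipocyte genes with the miR-708 inhibitor with length matching (0.10, percentile 97.8); the cause was not tested. Stricter thresholds lower the counts by construction. At q below 0.01, 575 genes were lower for miR-182, 413 higher and 200 lower for miR-203, and 414 higher and 269 lower for miR-708. With an absolute log2 fold change of at least 1, the higher and lower genes numbered 394 and 178 for miR-182, 140 and 70 for miR-203, and 114 and 74 for miR-708. Shared higher and lower genes at q below 0.01 numbered 380 and 164 for miR-182 with miR-203, 385 and 226 for miR-182 with miR-708, and 290 and 145 for miR-203 with miR-708; with the minimum change they numbered 104 and 41, 100 and 57, and 73 and 31. The seed shift left the range of random sets for miR-182 with 8mer sites alone (-0.047, percentile 0.665), and with matching on expression alone for miR-182 (-0.025, percentile 0.77) and miR-708 (-0.037, percentile 0.01), each time on the lower side; the cause was not tested. Depth is unknown, so how far it limits calls of low genes, such as the cell cycle and interferon genes near 1 FPKM, is not shown.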

Other observations

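The tests of shared control noise, adipocyte share, low control values and macrophages, and the 7 gene groups described next, were chosen only after their results were seen, and length and GC matching and the snoRNA test were chosen after the data but before their own results were seen. Genes of class I antigen presentation stood higher with all 3 inhibitors: of 17, the authors' deposited tables called 13, 11 and 9 higher for miR-182, miR-203 and miR-708 and none lower, with median log2 ratios of 1.24, 0.81 and 0.71. B2m, the light chain of class I molecules, stood at 253 FPKM in the control and at 735, 487 and 512 FPKM with these inhibitors. H2-Q genes in this group share sequence with near-identical copies, as do replication histones, and their single values are uncertain. Of 8 complement genes 7, 6 and 6 were called higher and none lower (medians 1.11, 0.81 and 0.74), and C3 stood at 130 FPKM in the control and at 284, 235 and 241 FPKM. Replication histones had 10 of 25, 4 of 20 and 5 of 20 measured genes called higher and none lower (medians 0.62, 0.40 and 0.28). Among 16 imprinted genes 7, 5 and 5 were called higher and none lower (medians 0.48, 0.29 and 0.29), and Cdkn1c, an inhibitor of cyclin-dependent kinases, stood at 16.2 FPKM in the control and at 37.8, 36.7 and 34.6 FPKM.

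Among 28 genes of hypoxia and glycolysis, the authors' deposited tables called 9, 4 and 6 lower and 1, 1 and 0 higher for miR-182, miR-203 and miR-708 (medians -0.25, -0.10 and -0.14). Ero1l, an oxidase of protein folding in the endoplasmic reticulum, stood at 1150 FPKM in the control and at 323, 623 and 585 FPKM, and Vegfa, an angiogenic growth factor, at 564 FPKM in the control and at 334, 391 and 377 FPKM, called lower for miR-182; the difference between inhibitors was not tested. Transcripts of the mitochondrial genome went both ways, with 5 higher and 4 lower, 4 higher and 1 lower, and 7 higher and 2 lower of 36 (medians -0.22, -0.10 and 0.081). Their summed FPKM was higher with each inhibitor, at 476736 in the control and 541032, 536410 and 619450, opposite in sign to the medians for miR-182 and miR-203. The transfer RNA mt-Ts1, not called in any comparison, held the largest part of the sum, with 177842 FPKM in the control and 262811, 239934 and 281546 FPKM. For miR-182 and miR-203 its difference from the control was larger than that of the sum. The other transcripts together therefore stood lower than in the control for miR-182 and miR-203, and higher for miR-708. The sum is not read as a change of mitochondrial transcripts as a whole.

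The changes shared by the 3 inhibitors were weighed against 3 technical explanations. Noise in the shared control samples as the whole cause, if independent between genes, predicts no correlation between contrasts without a common sample. The contrast of miR-182 over miR-203 correlated with miR-708 over control at r = 0.33 across genes, which argues against such independent noise as the whole cause. The pair with miR-203 over miR-708 gave -0.065, so for the changes shared by miR-203 and miR-708 control noise cannot be told apart. Differences between samples that move many genes together could also give such correlations, and the test cannot exclude them. Length or GC bias predicts that list medians fall back into the range of random lists once these are matched, yet 11 of the 11 lists outside that range for miR-182 stayed outside. With the miR-182 inhibitor, a lower share of adipocytes as a whole does not by itself account for the lower Ucp1 and Cidea. Their log2 ratios of -1.57 and -2.38 lay below the lowest of 20 general adipocyte genes (-0.54). That list cannot address a change in the kind or maturation of the adipocytes, and the comparison was not made for miR-203 and miR-708. For the higher precursor and matrix genes, a lower share of adipocytes cannot be told apart from a change within cells. The general adipocyte median was 0.035 with the miR-182 inhibitor, and a small share of precursors could grow without lowering it. What stays open as hypotheses, untested by this design, are an effect of each microRNA, an effect of the oligonucleotides that all 3 inhibitors share, and a difference in culture state such as maturation.

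The higher interferon genes may mark a response of the cells to the inhibitors or a difference between cultures that the design does not separate. The interferon median of miR-182 over miR-203, which uses no control sample, was 1.16, at percentile 100 of random lists. This argues against low values in the control alone as the cause of the whole rise with miR-182. Against the control, 13 members were measured for miR-203 and for miR-708. Some of the 17 members therefore entered through their miR-182 value, which favours a higher median. For the rises with miR-203 and miR-708, low control values cannot be told apart from like effects of both inhibitors, since the median of miR-203 over miR-708 was -0.050, at percentile 11.1. Macrophages brought in with the miR-182 inhibitor cultures would raise their own transcripts, yet the 11 macrophage markers with a value summed to 8.45 FPKM in the control and 5.32 FPKM with the miR-182 inhibitor, a ratio of 0.629, while Ifi27l2a alone went from 25.9 to 241 FPKM. Whether the oligonucleotide sequences differ in how they stimulate such genes was not tested.

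In the miR-203 samples, 6 of 7 loci of structural RNAs or thought to take reads like ribosomal RNA were called higher in the authors' deposited table (median log2 ratio 1.41), against 0 of 7 for each of miR-182 and miR-708 (medians -0.12 and -0.063). Mir5105 stood at 66947 FPKM in the control and 178253 FPKM with the miR-203 inhibitor, Rn7sk at 11.4 and 32.0 FPKM and Rpph1 at 9.11 and 31.6 FPKM. More RNA without poly(A) tails in these libraries is a candidate explanation. Among 131 snoRNA, scaRNA and snRNA genes the median log2 ratio for miR-203 exceeded the mean of the other 2 comparisons by 0.22, but their interquartile range was -0.68 to 0.73 and 0 were called higher, so this cannot be told apart from a change in the 7 loci themselves. No biological explanation was tested for it.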
